A study of Mus musculus with 8 samples.

How the data were processed

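Total RNA from 8 samples of cultured mouse bone marrow cells, 4 of healthy and 4 of streptozotocin-diabetic origin, was labelled with biotin and hybridised to Illumina Sentrix bead arrays, per the labels' protocols. The labels give 6 to 10 mice per group in each experiment of the study and place its histology at 28 to 30 weeks of diabetes. They do not say which mice gave which array.

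The deposited table holds, per the file headers, the average signal intensity of each probe on each array, its detection p-value, its bead number and the standard error over beads. The signal intensity was written by BeadStudio, per the submitters' processing notes, and its version and settings are not given in the sources used here. The deposited intensity values are linear, positive and not normalized between arrays, with mean signals from 301.6 to 458.6. The deposited detection p-value compares each probe with the array's negative controls. A second table holds the authors' processed intensity values for 10189 of the 24611 probes, which have the same sorted values on every array (median 228.8 on each) and correlate with the signals at 0.999 on the array of lowest correlation. How its probes were chosen is not given in the sources used here, and 105 of the tested probes are not in it. All per-sample columns were matched to the samples by the names in the labels, and 0 were left unused.

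Background was corrected with the normexp model fitted from the detection p-values, an offset of 16 was added, and arrays were quantile normalized and put on the log2 scale (neqc in limma 3.58.1, R 4.3.3). Probes with a detection p under 0.01 on at least 4 of the 8 arrays were tested, 9478 in all, of which 8003 were detected on all 8. Differences are diabetic minus healthy and were tested with lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes near background are understated because of the offset. A probe detected on no array of a group has only a bound there. Probes were named through the unversioned transcript accession in the table of current RefSeq genes (assembly GRCm38.p6, used for names only) for 20511 probes, by the file's symbol for 3871, and 230 had no symbol. The last include 1 of the 20511, whose identifier names 18S ribosomal RNA while its accession names another gene, so its symbol was not used. The files name no genome build, so no coordinates are given. Of 8069 genes with a tested probe, 1156 had several, and the probe with the highest mean over all 8 arrays stood for the gene. Levels of different genes are not set against each other as amounts of RNA.

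Before the data were examined, 36 gene lists were fixed, of which 31 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 between genes, and again with an estimated correlation and with fry. In camera without the block the estimated correlation gave adjusted p = 0.986 for every tested list, so failing it says little of a single list. The genes named were fixed by rule in advance. They are the 10 of lowest p in each direction, since none was called without the block, the up to 4 members of lowest p in 10 lists, and 9 identity markers. Of these lists 1, with its members, and several other genes are not reported here, although they took part in every fit and adjustment. Other list members that passed with the replicate block are named besides, chosen after their values were seen. Older symbols fixed with the lists were taken as the same gene.

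The labels number the replicates in each group, without saying that a number marks a shared mouse, litter or day. Deviations from the group means correlated across probes between arrays of the same number at 0.70, 0.44, 0.33 and 0.35 for replicates 1 to 4, each above 0.1, which is the criterion for pairing, so the fit with the replicate block is given beside the fit without it. Healthy replicate 3 correlated more with diabetic replicate 2, at 0.41, and healthy replicate 2 correlated with diabetic replicate 3 at 0.33. Both exceed 0.1, so the criterion does not single out pairing by number. Without the replicate 1 arrays the same-number values were 0.18, 0.04 and 0.30 for replicates 2 to 4, so the pairing rests largely on replicate 1. No arrays agreed within bead error: of the tested probes at least 26.3% differed by more than 2 standard errors in each pair of arrays.

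The probe index of an array is the median, over 654 pairs of probes of 1 transcript that lie over 200 bases apart, of the upstream minus the downstream log2 signal, each centred over arrays. Groups were compared on it with an exact permutation test over 70 arrangements. The calculations were tested on simulated data with 9478 probes and 4 arrays per group. Without the block 77 of 100 probes changed by a log2 of 1 and 96 of 100 changed by 2 were recovered, with 9 false calls, and with the block 85 and 94, with 7 false calls. A glycolysis list shifted by 0.5 was recovered with 0 other lists called. The simulated noise was independent between probes, so this does not test list calls among correlated genes. Nor does it give the recovery where many probes of an array move together. In the real fit without the block 124 probes changed by more than a log2 of 1 and 0 were called. Figures were drawn with matplotlib 3.10.9.

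Alternatives covered normalization, the authors' processed values, the offset (50), the detection filter, array weights, variance modelling, the threshold, the choice of probes and each array left out in turn. Slides are not named in the table, so a slide block was not fitted. Fits without replicate 1, without each pair, without upstream-class probes and with the probe index as a covariate, and an estimated correlation for each setting that called a list, were added after the data were seen.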

Results

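Bone marrow cells from healthy mice and from mice made diabetic with streptozotocin, a toxin that destroys the insulin-producing beta cells of the pancreas, were selected for endothelial progenitors and kept for 10 days in a culture that favours endothelial cells. Their total RNA was measured on Illumina bead arrays, on which each gene is read by 1 or a few probes carried by many beads. There were 4 arrays of healthy and 4 of diabetic origin, labelled as biological replicates 1 to 4 of each group. The labels do not say how the cultures or mice map to the arrays, so p-values measure the spread between these samples, which may in part be technical. The median bead number per probe was 34 or 35 on every array. Between 9014 and 9501 of 24611 probes were detected on the healthy arrays and between 9115 and 9785 on the diabetic arrays. The number of arrays limits the precision. The comparison of the groups addresses how streptozotocin diabetes changes the cells that grow from the marrow under these conditions.

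Colec12, a scavenger receptor, was 2.56-fold higher in diabetic cultures, at 7.80 ± 0.34 against 6.44 ± 0.27 in healthy cultures (log2 signal, SD, n = 4). Gsk3b, the kinase that holds glycogen synthase inactive until insulin signals, was lower at 8.05 ± 0.36 against 8.90 ± 0.18. Nqo1, a quinone reductase of oxidant defence, was higher at 7.36 ± 0.12 against 6.57 ± 0.35. All 4 diabetic arrays lay beyond all 4 healthy arrays for each of these genes. The same held for 1194 of 9478 tested probes, or 12.6%, where chance gives 2.86% for a single probe. Probes vary together across arrays, so this excess is not a test, and the share in other splits of the arrays was not counted. None of these genes passed without a replicate block (limma adjusted p = 0.104 for each). Nqo1 was read by a probe of a class that lies further upstream in transcripts, described below. Neither the insulin nor the oxidant defence list passed as a whole.

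After adjustment over all 9478 probes, limma called 0 probes without a replicate block, with a smallest adjusted p of 0.104. At an unadjusted p under 0.05 there were 2034 probes, 1042 higher and 992 lower in diabetic cultures, where 473.9 would arise by chance. With the replicate number as a block, 1407 probes for 1310 genes passed, 759 higher and 648 lower in diabetic cultures, and 3184 lay under an unadjusted p of 0.05. Without the class of probes that lies further upstream in transcripts, the balance turned, with 454 higher and 553 lower with the block, and 720 higher and 940 lower at an unadjusted p under 0.05 without it. In what follows, rose and fell are used of genes that passed in the fit with the block, and none of them passed over all probes without it. Standard errors are those of the fit without the block unless stated, so a change that passed with the block can be smaller than its standard error. The blocked count fell to 0 when the pair of replicate 2 or that of replicate 4 was left out (2349 and 2353 probes at an unadjusted p under 0.05), and it was 610 without replicate 1. Without the block, 368 probes passed when diabetic replicate 3 was left out and 0 when any other single array was, and the unadjusted count was 1315 without diabetic replicate 4. Array weights gave 972 calls without the block.

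**Figure D1:**
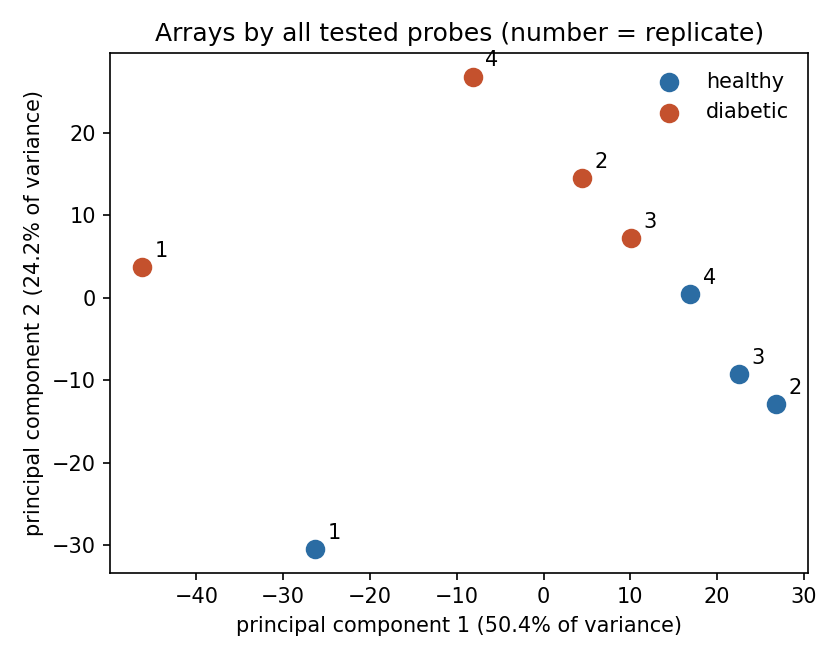
First 2 principal components of the log2 signals of all tested probes, 1 point per array, coloured by group and numbered by replicate, with each axis giving its share of the variance (50.4% and 24.2%). Both arrays of replicate 1 lie at the low end of the first component, at -26.3 (healthy) and -46.2 (diabetic), and diabetic arrays lie above the healthy array of the same number on the second.

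The 10 genes of lowest p in each direction are values that did not pass over all probes without the block (adjusted p = 0.104 for each in limma) and passed with it (adjusted p from 0.0185 to 0.0213). Among those that were higher in diabetic cultures, after Colec12, were Cav2, a caveolin of membrane pits, by 1.18 (SE 0.21, log2), Acadl, the long-chain acyl-CoA dehydrogenase of fatty acid oxidation, by 0.98 (SE 0.17), Cul4a, a scaffold of ubiquitin ligases, by 0.98 (SE 0.16), and Tmed2, a cargo receptor of the early secretory pathway, by 0.94 (SE 0.16). Dynlt1b, a dynein light chain with near-identical gene copies that the probe may not tell apart, Ctps2, Txndc7, Gigyf2 and Hnrnpa1, an RNA-binding protein with many processed copies in the genome, were higher by 0.70 to 0.79. Txndc7 is an older name of the disulfide isomerase Pdia6, and this probe was not counted in the endoplasmic reticulum stress list. Cav2 and Ctps2 were detected on 1 healthy array each, Acadl and Cul4a on 2, and Txndc7 and Gigyf2 on 3, so their differences rest on signals near background in healthy cultures. Among the genes that were lower were Bcat2, the mitochondrial transaminase of branched-chain amino acids, by -1.02 (SE 0.18), B230208H17Rik by -0.96 (SE 0.14), the protocadherin Pcdh1 by -0.92 (SE 0.16), Tap1, a peptide transporter for antigen presentation, by -0.87 (SE 0.16), and Eif4ebp2, a repressor of cap-dependent translation, by -0.81 (SE 0.13). The autophagy kinase Ulk1, the chromatin remodelling subunit Smarcd1, the transporter Slc12a9, the histone chaperone Daxx and the calcium channel Orai1 were lower by -0.73 to -0.54. A further probe of Pcdh1 read -0.62, and a further probe of Tmed2 read 0.39. Among the higher genes, the probes of Txndc7, Gigyf2, Ctps2, Dynlt1b, Acadl and Cav2 start at bases 9 to 173 of the transcript. Those of Tmed2, Hnrnpa1, Cul4a and Colec12 start at bases 532 to 1838. Among the lower genes, the Ulk1 probe starts at base 18 and the others at bases 1223 to 3567. Upstream probes read higher on the diabetic arrays, as described below, and position was not separated from these changes.

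**Figure D2:**
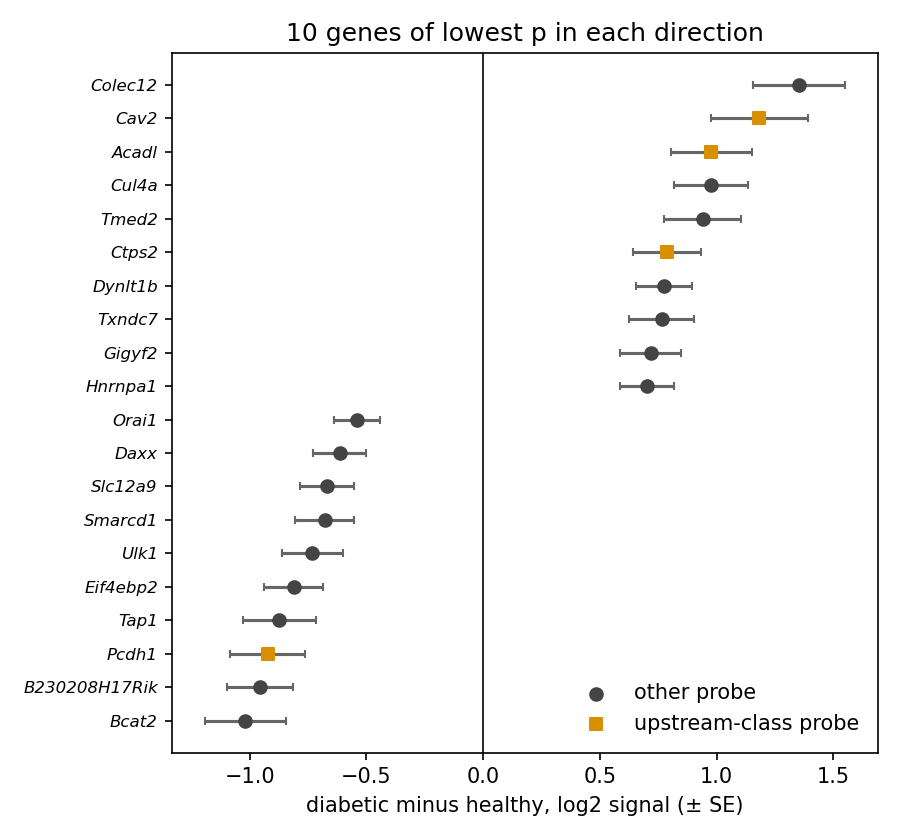
Diabetic minus healthy log2 signal of the 10 genes of lowest p in each direction, with bars of 1 standard error from the fit without the block (4 arrays per group). Colec12 stands highest at 1.35 and Bcat2 lowest at -1.02. Squares mark probes of the class whose median start lies further upstream in transcripts (Acadl, Cav2, Ctps2 and Pcdh1), although the Pcdh1 probe starts at base 3567.

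Probe position within the transcript differed between the groups. Over 654 pairs of probes for the same transcript, the upstream probe relative to the downstream probe read higher on the diabetic arrays, with an index of 0.12 ± 0.16 against -0.12 ± 0.05 (log2, SD, n = 4), a difference of 0.25 that gave p = 0.0286 in a two-sided exact permutation test, the smallest p that 4 against 4 arrays allow. Over the 238 pairs without a probe of the class described next the difference was 0.22, the groups overlapped and the exact permutation p was 0.0571. The index was 0.31, 0.06, -0.06 and 0.18 for diabetic replicates 1 to 4 and -0.09, -0.16, -0.17 and -0.07 for the healthy ones. A class of 1153 probes with short identifiers started at a median of base 611 of the transcript, against base 1663 for the 8325 others, and its median change was 0.17 against -0.04. In the blocked fit 22.6% of that class passed as higher and 3.73% as lower, against 5.98% and 7.27% of the other probes. With each array's index as a covariate the blocked fit called 0 probes, and 982 lay under an unadjusted p of 0.05, with larger standard errors (median 0.25 against 0.11) and no smaller changes (median size 0.26 against 0.20). The genes read by this class are marked below as upstream-class. The mark follows the identifier and not the position of each probe. Marked probes of Pcdh1 and Cxcl12 start at bases 3567 and 2873, and unmarked probes of Txndc7, Gigyf2, Ulk1 and Vwf at bases 9 to 18.

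In insulin and Akt signalling, Gsk3b fell by 0.85 (SE 0.18) and Pdpk1, the kinase that activates Akt, fell by 0.35 (SE 0.15), with limma adjusted p of 0.0185 and 0.0497 with the block. Pik3r2, a regulatory subunit of phosphoinositide 3-kinase, read -0.70 (SE 0.24) and did not pass (adjusted p = 0.0501 with the block). Of 13 tested members 6 were higher and 7 lower, and with the block 1 passed as higher and 2 as lower. Adjusted over the list alone, 1 passed without the block (Gsk3b) and 4 with it, and the list did not pass, with a mean of -0.08 and a camera adjusted p of 0.981.

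In oxidant defence 13 of 25 tested members were higher and 12 lower. Nfe2l2, the transcription factor that drives this programme, rose by 0.91 (SE 0.23), Nqo1 rose by 0.79 (SE 0.17), and the mitochondrial peroxiredoxin Prdx3 rose by 0.33 (SE 0.17). The secreted glutathione peroxidase Gpx3 fell by 0.46 (SE 0.16) and the mitochondrial thioredoxin Txn2 fell by 0.38 (SE 0.10). Nfe2l2 and Nqo1 were both read by upstream-class probes. Adjusted over the list alone, 3 passed without the block (Nfe2l2, Nqo1 and Txn2) and 5 with it, and the list did not pass (mean 0.06, camera adjusted p = 0.824). Without upstream-class probes its mean was -0.03. Among NADPH oxidase subunits and receptors for glycated proteins, 8 of 11 were lower and Stab1, a scavenger receptor, fell by 0.87 (SE 0.48), with a list mean of -0.13 and a camera adjusted p of 0.824.

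**Figure D3:**
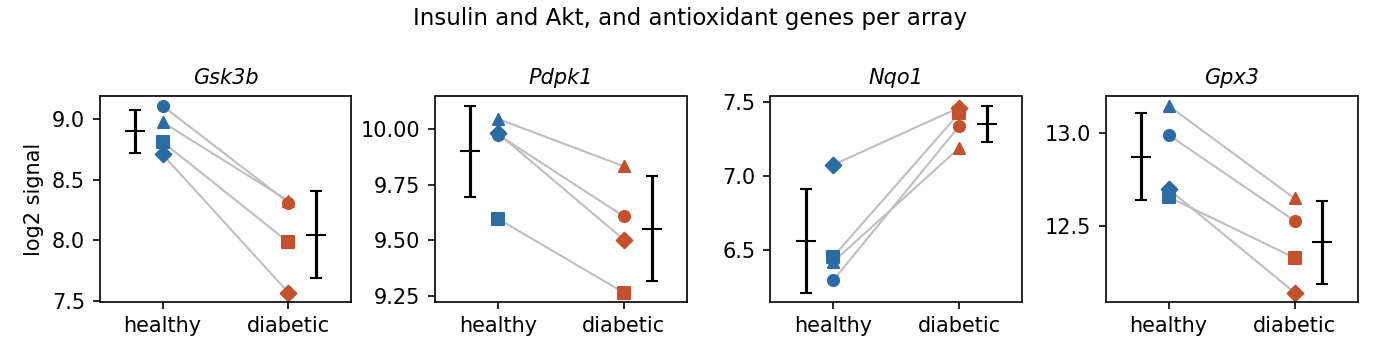
Log2 signal of Gsk3b, Pdpk1, Nqo1 and Gpx3, genes of the insulin and Akt and the oxidant defence lists, on each array, with grey lines joining arrays of the same replicate number, marker shapes for the replicate (1 square, 2 circle, 3 triangle, 4 diamond) and black bars for the mean and SD of 4 arrays. Gsk3b ranges from 8.71 to 9.11 on healthy and from 7.57 to 8.33 on diabetic arrays, and the lines of each gene run in 1 direction.

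Genes of endoplasmic reticulum stress formed the list that passed with the block. Of 14 tested members 12 were higher in diabetic cultures, the list mean was 0.28 higher (0.17 without diabetic replicate 1), and camera gave adjusted p = 0.0194 with the block and 0.404 without it. With an estimated correlation between genes the blocked list gave a camera adjusted p of 0.929, so the call did not hold under that setting. The estimate with the block was 0.14, above the preset 0.01. Without the block camera gave adjusted p = 0.986 for every tested list under that setting. There the estimate for this list was -0.014, under the preset, so a high correlation between its genes is not what gave 0.986. The setting was not tried on simulated data and cannot decide the call. Asns, the asparagine synthetase, rose by 0.71 (SE 0.34), Chac1, which degrades glutathione, by 0.72 (SE 0.66), Trib3, a pseudokinase induced by Atf4, by 0.71 (SE 0.78), and Edem1, of misfolded protein disposal, by 0.72 (SE 0.27, upstream-class). The list mean was highest on diabetic replicate 1, at 9.06, the array with the highest probe index, and healthy replicate 1 had the highest healthy mean, at 8.69.

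Genes of oxidative phosphorylation and the citric acid cycle had the smallest list p without the block. Of 33 tested members 26 were higher, by a mean of 0.11, with a camera adjusted p of 0.131 without the block and 0.0568 with it. Idh3g, of isocitrate dehydrogenase, rose by 0.78 (SE 0.22), cytochrome c (Cycs) rose by 0.51 (SE 0.18) and Cox6c rose by 0.51 (SE 0.15), and with the block 3 members passed as higher and 1 as lower. The list passed in camera when healthy replicate 1 was left out (adjusted p = 0.0228) and without a detection filter (adjusted p = 0.0299). It also passed with the block when upstream-class probes were left out (camera adjusted p = 0.0474). None of these calls held with an estimated correlation (camera adjusted p = 0.826, 0.992 and 0.982). Of 21 glycolysis genes 9 were higher, with a mean of 0.02, a median of -0.06 and an upward camera direction at adjusted p = 0.877, and Pgk1 rose by 0.49 (SE 0.14), Pfkp by 0.44 (SE 0.36, upstream-class) and the glucose transporter Slc2a1 by 0.38 (SE 0.28). In fatty acid oxidation 10 of 17 were higher (mean 0.07, and 0.03 without healthy replicate 3, camera adjusted p = 0.877), and Etfdh rose by 0.53 (SE 0.22) and the lipid droplet protein Plin2 by 0.45 (SE 0.28). In cholesterol synthesis 10 of 18 were lower (mean -0.05, camera direction upward, adjusted p = 0.951), where Mvd fell by 0.78 (SE 0.35) and Insig1, which restrains the pathway, rose by 0.93 (SE 0.22), and with the block 1 member passed as higher and 2 as lower. In lipid efflux 9 of 11 were lower (mean -0.21, camera adjusted p = 0.824), and Pltp fell by 0.61 (SE 0.29). Adjusted over the list alone and without the block, Acadl (upstream-class) and Insig1 passed in their lists and no gene of the other lists of this paragraph did.

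Endothelial and macrophage genes were both present. Pecam1, Cdh5, Vwf, Cd68 and Csf1r were detected on all 8 arrays, while Kdr, Tek, Nos3 and Ptprc were detected on 0. Of 19 tested endothelial genes 11 were higher and 8 lower, with a mean of 0.06 and a camera adjusted p of 0.877. Vwf fell by 0.74 (SE 0.37, adjusted p = 0.0407 with the block in limma) and the scavenger receptor Stab2 fell by 0.65 (SE 0.21, adjusted p = 0.0185). Emcn, an endothelial sialomucin, read 0.91 (SE 0.52, and 0.48 without diabetic replicate 1) and Mcam -0.29 (SE 0.19, and -0.09 without healthy replicate 2), and neither passed. Pecam1 read 7.42 ± 0.75 in diabetic and 7.04 ± 1.01 in healthy cultures and Cdh5 7.38 ± 0.88 and 7.19 ± 0.89 (SD, n = 4), differences within the spread. Without both replicate 1 arrays the endothelial mean was -0.28, Pecam1 read -0.37 and Cdh5 -0.53, and none passed. Of 13 junction genes 8 were higher (mean 0.09, camera adjusted p = 0.824), and Jam2 rose by 0.87 (SE 0.24). Pkp4 read -0.46, Jup -0.36 and Ctnna1 0.20, and none of them passed.

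Of 24 macrophage genes 15 were higher, with a mean of 0.08 and a camera adjusted p of 0.684. The protease Ctss rose by 0.66 (SE 0.15) and Cd84 rose by 0.34 (SE 0.18), while the mannose receptor Mrc1 fell by 0.45 (SE 0.25), the complement gene C1qa fell by 0.47 (SE 0.28) and Pld4 fell by 0.45 (SE 0.35). Csf1r read 9.38 ± 0.26 against 9.04 ± 0.07 (other probe 0.02 for the difference) and Cd68 12.29 ± 0.30 against 12.17 ± 0.36 (SD, n = 4), and neither passed, like Tyrobp at 0.51 (SE 0.18) and Lyz2 at 0.27 (SE 0.10). Neutrophil precursor genes were lower for 10 of 12 members, by a mean of -0.64 (camera adjusted p = 0.733), and Prtn3, the granule protease, fell by 0.89 (SE 0.39). Lcn2 read -1.12 (SE 0.63), Retnlg -0.98 (SE 0.80) and Mpo -1.24 (SE 1.01, other probe -1.06), and none passed. With single arrays left out they ranged from -1.64 to -0.58, from -1.67 to -0.48 and from -2.04 to -0.44, and the list mean was -0.14 without diabetic replicate 1 and -0.18 without healthy replicate 2. Without healthy replicate 1 this list passed as lower (mean -1.34, camera adjusted p = 0.0228), but not with an estimated correlation (adjusted p = 0.826 with an estimated correlation). The probes that stood for Prtn3, Retnlg and Mpo were each detected on 3 healthy and 2 diabetic arrays, so their differences rest in part on signals near background. All 5 B cell genes were lower (mean -0.55, camera adjusted p = 0.733), where both Igh-6, the immunoglobulin M heavy chain, at -1.74 (SE 0.75) and Cd79b at -0.50 (SE 0.37) fell.

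Of 19 stromal genes 13 were lower, by a mean of -0.19 (camera adjusted p = 0.824). Sparc was not detected on any healthy array and on all 4 diabetic ones, at least 1.28-fold higher (5.85 ± 0.29 against 5.15 ± 0.24, SD, n = 4, limma adjusted p = 0.0188 with the block), a bound that sets its diabetic mean against the lowest detected signals of the healthy arrays. Bgn read -0.50 (SE 0.18), Col6a2 -0.81 (SE 0.35) and Pdgfrb -0.33 (SE 0.14), and none passed. The stromal mean was -0.03 without healthy replicate 2. Of 7 osteoblast genes 5 were lower (mean -0.37, and -0.07 without healthy replicate 3, camera adjusted p = 0.877), and Alpl, the alkaline phosphatase, fell by 0.94 (SE 0.23). Megakaryocyte genes were lower for 6 of 8 (mean -0.35, camera adjusted p = 0.909), although Pf4 rose by 0.72 (SE 0.22). Adjusted over the list alone with the block, 1 megakaryocyte gene passed as higher (Pf4) and 4 as lower, 2 erythroid genes passed as lower and 0 neutrophil precursor genes passed. Osteoclast genes were lower for 4 of 6 (mean -0.13, camera adjusted p = 0.824), and adipocyte genes for 5 of 7 (mean -0.17, camera adjusted p = 0.877), where Scd1 fell by 0.68 (SE 0.35). Lists with fewer than 5 tested members had no test, and their means were -0.36 for 2 dendritic cell genes, -0.05 for 2 mast cell genes, -0.27 for 3 T and NK cell genes and -0.61 for 2 erythroid genes. Of the sex-linked transcripts Ddx3y, Eif2s3y, Kdm5d and Uty were detected on 0 arrays, and Xist had no probe. Adjusted over the list alone and without the block, Ctss, Alpl and no other gene of the cell type lists passed.

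Cell cycle genes separated both replicate 1 arrays from the rest more than they separated the groups. The list mean was 6.92 on healthy and 6.76 on diabetic replicate 1, against 8.05 to 8.07 on the other healthy and 7.99 to 8.06 on the other diabetic arrays. Between the groups 14 of 24 members were lower, with a mean of -0.07, and camera, which compares a list with all other genes, gave an upward direction and adjusted p = 0.909. Mcm2, of the replication helicase, fell by 0.55 (SE 0.31, -0.27 without diabetic replicate 1), the proliferation marker Mki67 fell by 0.46 (SE 0.68) and Birc5 fell by 0.47 (SE 0.61), while the ribonucleotide reductase subunit Rrm2 rose by 0.38 (SE 0.20, and 0.25 without healthy replicate 2). Rrm2 did not follow the list on replicate 1, where it lay 0.62 (healthy) and 0.53 (diabetic) above the mean of the other arrays and the other members lay below. Tyms read 0.39 (SE 0.28, upstream-class, other probe 0.57) and Pcna 0.19 (SE 0.14), and neither passed. No cell cycle gene passed without the block when adjusted over the list alone.

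**Figure D4:**
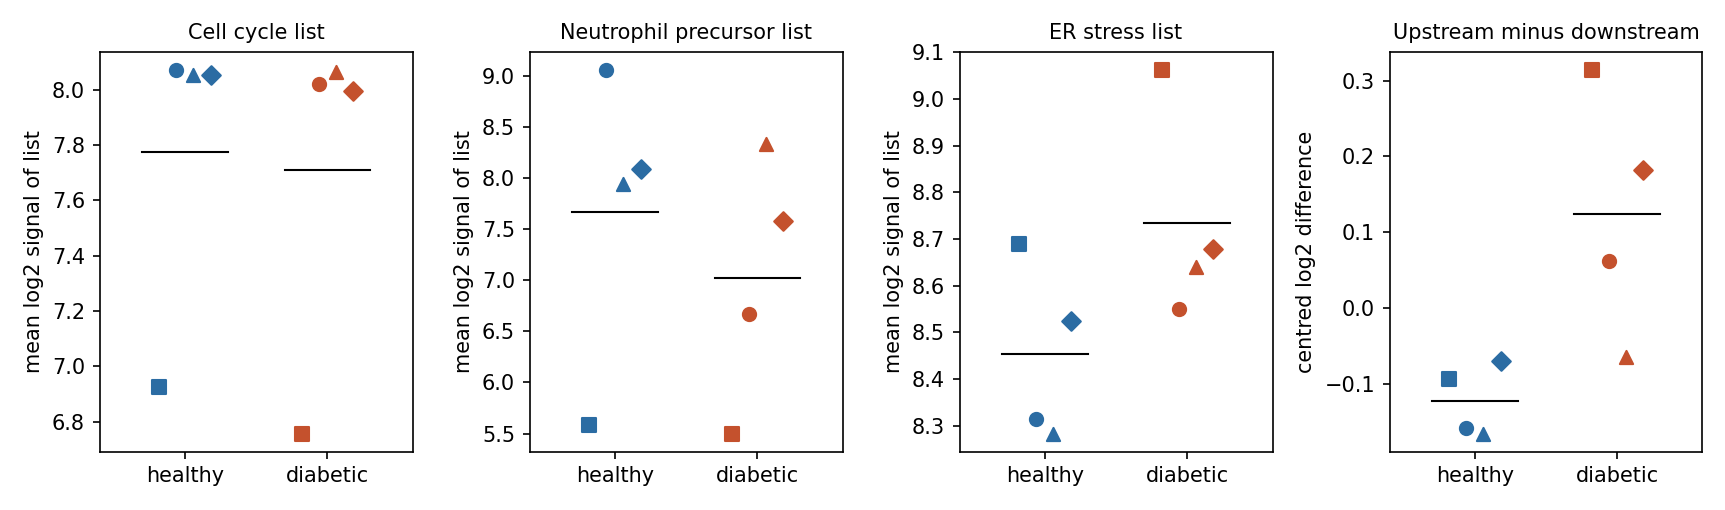
Mean log2 signal of the cell cycle, neutrophil precursor and endoplasmic reticulum stress lists and the upstream-minus-downstream probe index on each array, with marker shapes for the replicate (1 square, 2 circle, 3 triangle, 4 diamond) and lines for group means. Replicate 1 of both groups is lowest for the cell cycle list (6.92 and 6.76) and the neutrophil list (5.58 and 5.50), and for the index the lowest diabetic array, replicate 3 at -0.06, lies next to the highest healthy array, replicate 4 at -0.07.

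Niche factors of blood stem cells included the chemokine Cxcl12 at -0.91 (SE 0.67, upstream-class, other probe -0.59, and -0.31 without healthy replicate 2), Csf1 at 0.37 (SE 0.15), Spp1 at 0.26 (SE 0.15) and Cdh2 at 0.26 (SE 0.17), and none of 9 tested members passed (mean -0.06, camera direction upward, adjusted p = 0.877). Of 18 angiogenic factors and receptors 11 were lower (mean -0.01, camera adjusted p = 0.877), and Vegfa rose by 0.50 (SE 0.44). Hypoxia genes were higher for 7 of 14 (mean 0.03, camera adjusted p = 0.909). Stem and progenitor genes were higher for 5 of 10 (mean -0.03, camera direction upward, adjusted p = 0.909), and the transcription factor Runx1 rose by 0.34 (SE 0.14). In p53 targets 10 of 19 were lower (mean -0.03, camera direction upward, adjusted p = 0.909), where Bbc3 fell by 0.54 (SE 0.12), Sesn1 fell by 0.41 (SE 0.48) and Ccng1 rose by 0.55 (SE 0.22). Of 27 basement membrane and proteolysis genes 15 were lower (mean -0.10, and -0.03 without diabetic replicate 4, camera adjusted p = 0.877), with falls of Lamb2 (-0.77), Serpine2 (-0.56), Ctsd (-0.51) and Mmp2 (-0.45) and rises of thrombomodulin, Thbd (0.73), and the urokinase receptor Plaur (0.59).

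Inflammatory genes were lower for 10 of 18 (mean -0.06, camera adjusted p = 0.980), with falls of Relb by 0.61 (SE 0.16) and Il10 by 0.50 (SE 0.68). Interferon response genes were lower for 14 of 19 (mean -0.11, camera adjusted p = 0.824), and the GTPase Igtp fell by 0.53 (SE 0.29). Class II antigen presentation genes were lower for 6 of 9 (mean -0.13, camera adjusted p = 0.824), and the costimulator Cd86 fell by 0.67 (SE 0.18). Immediate early and heat shock genes were higher for 11 of 18 (mean -0.02, median 0.04, camera direction upward, adjusted p = 0.877), with falls of Junb by 0.77 (SE 0.22) and Jund by 0.60 (SE 0.18). Adjusted over the list alone and without the block, Bbc3 and Cd86 passed in their lists, and no gene of the niche, angiogenic, hypoxia, stem cell, basement membrane, inflammatory, interferon and immediate early lists did. With the block and over the list alone, 1 p53 target passed as higher and 3 as lower, 2 class II genes as lower, 1 stem cell gene as higher and 1 as lower, 1 inflammatory gene as lower, and 0 angiogenic and 0 interferon genes. In total 0 of 31 tested lists passed without the block, with a smallest camera adjusted p of 0.131 and of 0.986 with an estimated correlation.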

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

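The tests of transcript ends, all those on the replicate 1 arrays and the fits without replicate 1, without upstream-class probes and with the probe index were chosen only after the result was seen. A single array stood far from the other 3 of its group in 12 of 182 comparisons, where chance gives about 9.1, since chance flags about 1 in 20 groups, and 8 of the 12 were replicate 1 arrays.

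On the healthy arrays replicate 1 stood apart in mean signal (458.6, against 301.6 to 324.8), the macrophage list (10.43 against 10.58 to 10.61), the cell cycle list (6.92), the glycolysis list (9.72 against 9.39 to 9.42), Pdpk1 (9.60 against 9.98 to 10.05) and Mcm2 (8.03 against 8.86 to 8.88). Healthy replicate 4 stood apart in Pcna (5.86 against 5.24 to 5.33). On the diabetic arrays replicate 1 stood apart in the cell cycle list (6.76) and the inflammatory list (8.999 against 9.10 to 9.12), replicate 3 in detected probes (9115 against 9684 to 9785) and in Smarcd1 (5.98 against 5.81 to 5.82), and replicate 4 in the basement membrane list (9.55 against 9.79 to 9.83).

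Both replicate 1 cultures had low cell cycle genes, and 91.7% of 24 members were lowest in replicate 1 of both groups, by a list mean of -1.13 in healthy and -1.27 in diabetic cultures. Neutrophil precursor genes were lower by -2.78 and -2.03, megakaryocyte genes by -2.23 and -1.62, and adipocyte genes were higher by 2.41 and 0.87. Shorter labelled RNA in both samples is argued against by the probe index, which was -0.0940 on healthy replicate 1, inside the range of its group, and highest of all on diabetic replicate 1, and a difference in overall signal by the mean signal of diabetic replicate 1, at 364.6 inside the range of its group. Whether the cultures held fewer cycling cells stays open, since the cell cycle genes that raised the question cannot also test it and the neutrophil and adipocyte values were not addressed. No biological explanation from the design was tested, since the replicate number is not a treatment.

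Upstream probes read higher on the diabetic arrays, by 0.25 in the probe index. Dim probes and the background correction are argued against, since pairs with both probes above the median level gave a change of 0.247 (two-sided exact permutation p = 0.0286, the smallest possible). Shorter labelled RNA in the healthy samples is consistent with a change that grew with the distance between the probes (rho 0.172 over 654 pairs, 95% interval 0.0927 to 0.250, permutation p = 0.0001, the smallest that the permutations can give; genes are not independent replicates), although the median change was 0.40 for pairs 1000 to 2000 bases apart and 0.16 beyond that. A different use of transcript ends in diabetic cultures cannot be told apart from this, because 74.3% of pairs were higher in diabetic arrays and the index moves with the groups, separating them completely over all pairs and with overlap over the 238 pairs without upstream-class probes (difference 0.22, exact permutation p = 0.0571). An effect of diabetes on the cells stays open and untested.

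Part of the calls of the fit with the replicate block may follow probe position. For 71.0% of 69 called downstream probes (exact 95% interval 58.8 to 81.3) the upstream probe of the same transcript had a change of the same sign, against 59.9% of all pairs. Of 186 called upstream probes 158 were higher and 28 lower, and 67.2% shared the sign of the downstream probe, which leaves open how many calls are changes of the whole transcript. The count in limma was 1007 without upstream-class probes (454 higher and 553 lower) and 0 with the index as a covariate (982 at an unadjusted p under 0.05). With the block and that covariate Colec12 read 1.81 (SE 0.35), against 1.35 (SE 0.16) with the block alone, each standard error from its own fit. The residual degrees of freedom were 2 against 3, and the median standard error over probes was 0.25 against 0.11, with no smaller changes (median size 0.26 against 0.20). What ended the calls was not separated, so the count of 0 does not show that they followed probe position.

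Chance was not excluded for the count at an unadjusted p under 0.05 in limma without the block, where 2 of 35 splits of the 8 arrays into 4 and 4 gave as many probes (2034 for the real split), and the highest other, with 2436, set healthy replicate 1 with diabetic replicates 1, 2 and 4. That split puts both replicate 1 arrays on 1 side, and the count without them was 2513 for the real groups. With the replicate block, the splits that part all 4 pairs number 8, too few for a share under 0.05, and 1 of them, the real one, gave 1407 calls, with 0 for the highest other. The other 7 differ from it in which member of each pair is called diabetic. For calls without the block the real counts were 0 probes and 0 lists, which all 35 splits reach whatever the data, so these counts say nothing of chance. Other splits called up to 1 probe and up to 10 lists. Most of them called at least 1 list at the preset correlation, so a list call made that way need not reflect the groups. Why they did so was not tested.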

How the results depend on the processing

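Leaving out both replicate 1 arrays, leaving out pairs under the block, removing upstream-class probes and using the probe index as a covariate were chosen only after the result was seen. Without a block limma called 0 probes under the other normalizations, the authors' processed values, an offset of 50, other detection filters, the trend and robust variance model, a threshold of 0.10, an added 2-fold minimum and 1 probe per gene, with 1763 to 3342 probes at an unadjusted p under 0.05 where these were counted. The count was 972 with array weights, 0 to 368 with single arrays left out, and 1407 with the replicate block. With the block it was 610, 0, 1109 and 0 without replicates 1 to 4 (535 and 887 of the 610 and 1109 shared with the 1407), 1007 without upstream-class probes and 0 with the index. Probes at an unadjusted p under 0.05 numbered 1315 to 2502 with single arrays left out, 3342 without a detection filter, 2349 and 2353 with the block and without replicate 2 or 4, 3184 with the block, 566 with the index and 982 with both. Lists called numbered 0 to 2 with single arrays left out, 1 without a detection filter (oxidative phosphorylation), 1 with the block (endoplasmic reticulum stress), and with the block also 0, 1, 0 and 1 without replicates 1 to 4, 2 without upstream-class probes, 2 with the index (cell cycle at 0.74 and cholesterol synthesis at 0.28) and 3 with the index and the block (endothelial at -0.91, interferon at -0.33 and adipocyte at 1.03), where the means of all but interferon had the opposite sign without the index. None of these list calls held with an estimated correlation, tried after the data were seen (adjusted p = 0.826 to 0.992). That setting called 0 lists with or without the block, so it does not sort these calls. Of 58 named genes 34 passed with the block, 30 with array weights and 23 without diabetic replicate 3, against 1407, 972 and 368 of 9478 probes. Most of the named genes were chosen for a low p in these same data, so their counts are not a check on them.

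The changes of sign that follow concerned values that did not pass without the block. With array weights the mean was -0.0547 for endothelial, 0.0519 for osteoclast and 0.12 for adipocyte genes and -0.10 for Cdh5. Without both replicate 1 arrays it was -0.28 for endothelial, 0.22 for adipocyte, -0.0313 for junction, -0.0235 for hypoxia and 0.0461 for immediate early genes, with Pecam1 at -0.37 and Cdh5 at -0.53. Without upstream-class probes it was -0.0265 for oxidant defence, -0.0133 for glycolysis and 0.0406 for niche genes. With the mean of all probes of a gene it was 0.0698 for osteoclast, 0.00063 for angiogenic and 0.0015 for stem cell genes, and with detection on all 8 arrays 0.0030 for p53 targets. With single arrays left out the range was -0.17 to 0.23 for endothelial, -0.90 to 0.0569 for megakaryocyte, -0.58 to 0.43 for adipocyte, -0.16 to 0.0716 for angiogenic, -0.0509 to 0.00533 for p53, -0.35 to 0.25 for cell cycle, -0.0294 to 0.11 for glycolysis, -0.15 to 0.0200 for cholesterol, -0.13 to 0.0238 for niche, -0.0672 to 0.00543 for stem cell, -0.000732 to 0.0645 for hypoxia and -0.14 to 0.0959 for immediate early genes, and -0.0584 to 0.75 for Pecam1, -0.0236 to 0.27 for Cd68 and -0.19 to 0.52 for Cdh5. Among lists whose sign held with every single array left out, the mean moved more than 1.5-fold for neutrophil precursor (-1.34 to -0.14), osteoblast (-0.66 to -0.0679), stromal (-0.35 to -0.0304), osteoclast (-0.26 to -0.0254), NADPH oxidase (-0.22 to -0.0143), interferon (-0.25 to -0.0445), junction (0.00217 to 0.16), macrophage (0.0269 to 0.16), endoplasmic reticulum stress (0.17 to 0.36), basement membrane (-0.13 to -0.0338), fatty acid oxidation (0.0307 to 0.12), lipid efflux (-0.27 to -0.12), insulin (-0.11 to -0.0407), oxidant defence (0.0274 to 0.0787), inflammatory (-0.0676 to -0.0280) and class II genes (-0.18 to -0.0859). Among single genes the value did so for Emcn (0.48 to 1.17), Mcam (-0.41 to -0.0905), Mcm2 (-0.76 to -0.27), Rrm2 (0.25 to 0.54), Tyms (0.25 to 0.68), Pcna (0.13 to 0.33), Lcn2 (-1.64 to -0.58), Retnlg (-1.67 to -0.48), Mpo (-2.04 to -0.44), Cxcl12 (-1.34 to -0.31), Spp1 (0.15 to 0.38), Cdh2 (0.13 to 0.34), Jup (-0.52 to -0.22) and Csf1r (0.21 to 0.42). The cause was not tested. A slide block was not run, since no slide is named, and signal near background limits the differences of genes detected on few arrays of a group.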

Other observations

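All tests and values given here were chosen only after the result was seen. Among 247 terms of the array's own annotation with 15 to 300 tested genes, genes of protein biosynthesis (155 genes, median change 0.05, camera adjusted p = 0.0367), structural constituents of the ribosome (128 genes, median 0.06, adjusted p = 0.0367) and the ribosome (82 genes, median 0.05, adjusted p = 0.0487) were higher in diabetic cultures without a replicate block in limma's camera. None held with an estimated correlation (camera adjusted p = 0.973 with an estimated correlation). That setting passed 0 of the gene lists as well, so it cannot decide these terms. With the block the adjusted p were 0.0134, 0.0214 and 0.0281, and without both replicate 1 arrays 0.122, 0.122 and 0.137. Of the 128 ribosome constituents 80 were higher and 48 lower, and 0 passed singly without the block. With the block 10 rose and 1 fell, no larger a share in either direction than over all tested probes (759 higher and 648 lower of 9478). Named after their values were seen, Rpl7a was higher by 0.72 (SE 0.22), Rpl36 by 0.61 (SE 0.16), Rps23 by 0.51 (SE 0.11), Rps4x by 0.48 (SE 0.12) and Rps3 by 0.43 (SE 0.14). Ribosomal protein genes have many near-identical copies, so their probes cannot be taken to read a single gene, and 7 of the 128 probes were upstream-class. Rps6ka1, a kinase, was the member that fell, by 0.55 (SE 0.26). The term also holds other genes that are not ribosomal proteins, such as Rps6ka3 and Gadd45a, and Nhp2 among those that rose.

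Of 19 endothelial genes 12 lay on opposite sides of the other arrays of their group in the replicate 1 cultures, 11 of them lower in healthy and higher in diabetic replicate 1, and 7 lay on the same side. In healthy replicate 1 Pecam1 lay at -1.77 from the mean of the other healthy arrays, Cdh5 at -1.37, Emcn at -1.52 and Esam at -2.49. In diabetic replicate 1 the same differences were 1.25, 1.52, 1.72 and 1.00, and the endothelial list mean was -0.90 for healthy and 0.46 for diabetic replicate 1. Vwf was lower in both, at -1.11 and -0.95, as were Mmrn1 (-1.04 and -0.96), Lyve1 (-0.52 and -1.88) and Stab2 (-0.45 and -0.49). Adipoq and Cfd, the adipocyte genes adiponectin and adipsin, were higher in both, by 4.03 and 5.23 in healthy and by 1.22 and 2.69 in diabetic replicate 1. The collagen-binding proteoglycan Dcn was lower in both, by -5.22 and -3.81. Whether the differences in endothelial genes belong to diabetes or to these cultures was not testable with 1 array of each.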
